A study of Mus musculus with 2 samples.

How the data were processed

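Single-cell RNA sequencing libraries of mouse thymocytes were analysed, 1 from a control mouse (WT) and 1 from a mouse with a deleted Pten enhancer (KO). The group of each library is its genotype label. Per the labels' protocols, red blood cells were lysed, part of each cell suspension was depleted with biotinylated antibodies against CD3 and CD4 and magnetic beads, and the depleted cells were mixed 1:1 with total thymocytes before library preparation (Chromium Single Cell 3′, v3). The deposited values are raw UMI counts per gene and cell barcode in filtered matrices made by Cell Ranger 3.0.2, per the file headers, against mm10, per the submitters' processing notes. Each matrix holds 31053 genes. The authors' annotation release, read length and any doublet step are not given in the sources used here. No cell annotation of the authors was used here.

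Cells with at least 500 genes and under 10% mitochondrial UMIs were kept (7842 WT and 6089 KO). Scrublet, as built into scanpy 1.11.5, marked 2 WT cells (0.026%) and 73 KO cells (1.20%) at its automatic threshold. The rule set beforehand was to leave that threshold where it marks under 0.5% of a library, so the cells with the highest scores were removed at 0.8% per 1000 barcodes, which took 560 WT and 355 KO cells. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, taken by dispersion in bins of mean expression (without antigen receptor segments, ribosomal, mitochondrial, haemoglobin and sex-linked genes and Pten), 30 principal components and 15 neighbours, Leiden clusters were drawn at resolution 1.0 for both libraries together, with no batch correction (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9).

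A cluster was named for the class whose markers had the highest mean log2 ratio to all other cells, among classes with at least 3 markers raised (log2 ratio above 0.5 and at least 20 CPM). A cluster whose 10 leading genes (by ratio, at least 50 CPM) held more markers of another class stayed unnamed. Antigen receptor genes were left out of the naming, a choice made after the clusters were seen. The cycling class was divided after the clusters were seen, at 500 CPM of Cd8a and 200 CPM of Il2ra. Classes with at least 200 cells in each library were compared, namely 5 named classes and cluster 9.

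UMIs were summed per class and library and given per 1000000 (CPM). A level has an exact Poisson interval, a ratio an exact conditional binomial interval of both counts, and a share an exact Clopper-Pearson interval, all at 95% and all covering counting error only. A ratio of shares has an approximate 95% interval, normal on the log scale, which also covers counting error only. A summed count under 3 was set to 3 for a ratio. With 1 library per genotype no test was made; a ratio compares these libraries, not the genotypes. Over all kept cells 3 UMIs amount to 0.0398 CPM in WT and 0.0496 CPM in KO. Phase calls used scanpy's cell cycle scores after each cell was thinned to 2000 UMIs, with shallower cells left out.

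Genes were named by a rule: Pten, then in each compared class the 8 highest and 8 lowest ratios (12 in the largest class) among genes with at least 50 CPM and 100 UMIs in a library. Antigen receptor, ribosomal protein, mitochondrially encoded, haemoglobin and sex-linked genes and genes with only a Gm number or Rik name were left out of that ranking. Up to 4 members of a list described were named, those with most UMIs or the largest ratios, and each neighbour of Pten with at least 20 UMIs. Gene lists covered Pten's neighbours, the PI3K, AKT and mTOR pathway, FOXO, MYC, ATF4, Notch, p53 and interferon targets, glycolysis, cholesterol synthesis, oxidative phosphorylation, S and G2/M phase, T cell receptor signals, rearrangement and DP identity, dissociation stress, apoptosis, sex-linked, haemoglobin, ribosomal and mitochondrial genes and markers of non-thymocyte cells. A list's median log2 ratio over members with at least 20 UMIs was set among 10000 random lists of the same size matched on mean expression in 20 bins, and is a description of these libraries. Markers, lists, rules and the alternatives not named below as added were fixed before the data were examined. The haemoglobin list and the erythroid and stromal markers had too few members with enough UMIs for a median of their own; the markers also entered the joint non-thymocyte list. The symbols 2810417H13Rik, Scart2 and Hn1 were not found in the files.

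Near-identical copies were found by comparing the last 300 bases of each gene's longest transcript (GENCODE vM21 annotation) with all other genes' transcripts; a gene with at least 25% of its 60-base windows in another gene (3005 of 30846) counts as having a copy. Reads from such ends cannot be assigned to 1 gene from their sequence alone. This definition was set after the data were seen.

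The ratio and list steps were tested on simulated Poisson counts drawn from the pooled summed profiles, with 200 genes altered per class. In resting DP-like cells (14910 genes), a true ratio of 0.5 gave a median of 0.497 and a true ratio of 2 gave 1.98, with 98% and 94% of intervals holding the true value. The simulation named 16 genes there, fewer than the 12 highest and 12 lowest named in that class in the data. All 16 were altered ones, and the longer naming used in the data was not simulated. Of 100 unaltered lists, 7% fell outside the middle 95% of random lists.

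Alternatives were other cell filters (none, or at least 1000 genes and under 5% mitochondrial UMIs, here called strict), no doublet removal, Leiden resolutions 0.6 and 1.6, clustering without cycle genes, classes carried over from WT cells alone, other scales (totals without ribosomal and mitochondrial genes, the median of gene ratios, the mean over cells), thinning to 2000 UMIs (3000 or none for phase calls), and other count minimums (25 CPM and 50 UMIs or 100 CPM and 200 UMIs for named genes, 100 UMIs for lists). Removal of the highest doublet scores by rate, listed as an alternative, became the reported step. Added after the data were seen were Scrublet's automatic threshold, ratios averaged within clusters with the WT library's UMIs as weights, and totals without copied genes. The deleted stretch was not located, as the labels give no coordinates.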

Results

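The data came from the thymus of C57BL/6 mice, littermates of about 6 weeks. Single-cell RNA sequencing (10x Genomics Chromium, 3′ v3 chemistry, which counts transcripts by unique molecular identifiers, UMIs) was run on a wild-type control (WT) and on a mouse with a deleted enhancer of Pten (KO). Pten encodes the lipid phosphatase that opposes phosphoinositide 3-kinase (PI3K) signalling. Each library was a 1:1 mix of total thymocytes and thymocytes depleted of cells bearing CD4 or CD3, so immature stages were enriched. The WT library held 8931 barcodes and 87245909 UMIs (median 4889 per barcode), and the KO library 7283 barcodes and 68092194 UMIs (median 4117). After filters and doublet removal, 7282 WT cells (75346254 UMIs) and 5734 KO cells (60488113 UMIs) remained. Both libraries carried the Y-linked Ddx3y (4470 and 4538 UMIs) and almost no Xist (4 and 5 UMIs). With 1 library per genotype, no difference has a replicate check and no test was made; each interval is a 95% interval that covers counting error only.

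Clustering gave 24 clusters, named by markers. They covered cells like early T-lineage progenitors and double-negative 2 cells (ETP/DN2-like), DN3-like cells, cycling thymocyte-like cells, resting CD4 CD8 double-positive (DP) cells, selected DP or immature single-positive (SP) cells and mature SP-like cells. Smaller clusters were like innate T, gamma-delta T, B, macrophage or monocyte and granulocyte cells, and clusters 9, 11 and 18 stayed unnamed. The innate T-like group pools clusters 17 and 23. Cluster 23 (7 WT and 13 KO cells) had little Cd3e (98 CPM, against 738 CPM in cluster 17), so its cells may not be T cells. Within every compared class the KO cells were the deeper ones, with median UMIs of 2042.5 in WT and 2716 in KO resting DP-like cells and of 25422.5 and 30797 in cycling thymocyte-like cells.

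The first question was whether the KO library held less Pten, and at which stages. Pten was lower in the KO library over all cells and in each immature class. The gap was widest in resting DP-like and in selected DP or immature SP-like cells, and none was seen in mature SP-like cells. Over all kept cells, Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160, plus strand, mm10) stood at 139 and 102 CPM (UMIs per 1000000 UMIs) in WT and KO, a KO to WT ratio of 0.735 (0.712 to 0.758). This all-cell ratio also carries the different cell mix of the libraries. Cycling thymocyte-like cells gave 49386512 of the 75346254 WT UMIs and 31456991 of the 60488113 KO UMIs. In resting DP-like cells the levels were 340 and 168 CPM, a ratio of 0.495 (0.458 to 0.535), and in selected DP or immature SP-like cells 245 and 102 CPM, a ratio of 0.417 (0.336 to 0.516). In mature SP-like cells they were 94.6 and 95.1 CPM, a ratio of 1.01 (0.845 to 1.2), so no difference was detected there. The ratios of the other compared classes (0.417 to 0.759) lay outside this counting interval, while a smaller difference could be missed at this depth. Most resting DP-like cells lay in cluster 1 in WT and in cluster 2 in KO; the Pten ratio was 0.44 (0.386 to 0.5004) in cluster 1 and 0.475 (0.424 to 0.533) in cluster 2.

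In the earlier stages the Pten ratio was 0.626 (0.538 to 0.727) in ETP/DN2-like, 0.689 (0.639 to 0.742) in DN3-like and 0.759 (0.724 to 0.796) in cycling thymocyte-like cells. The cycling class was split by its Cd8a and Il2ra levels after the clusters had been seen. Its Cd8a-high clusters (12, 15 and 22) had a ratio of 0.539 (0.466 to 0.623), its Il2ra-high cluster (14) 0.722 (0.618 to 0.843), and the clusters low in both (4, 6 and 7) 0.767 (0.727 to 0.81). Cluster 9, nearest to the selected DP or immature SP markers but with more mature SP markers among its leading genes, had 0.63 (0.486 to 0.815). In the innate T-like cells the ratio was 1.08, with an interval of 0.636 to 1.85 from 29 and 33 UMIs. Ranked from the lowest ratio among genes within 2-fold of its level, Pten was gene 1 of 1235 in resting DP-like cells, 1 of 1806 in selected DP or immature SP-like, 2 of 2166 in cycling thymocyte-like, 6 of 1580 in DN3-like and 943 of 2406 in mature SP-like cells. The labels give no coordinates for the deleted stretch, so it was not looked for in these counts and Pten is the only check of the genotype.

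**Figure D1:**
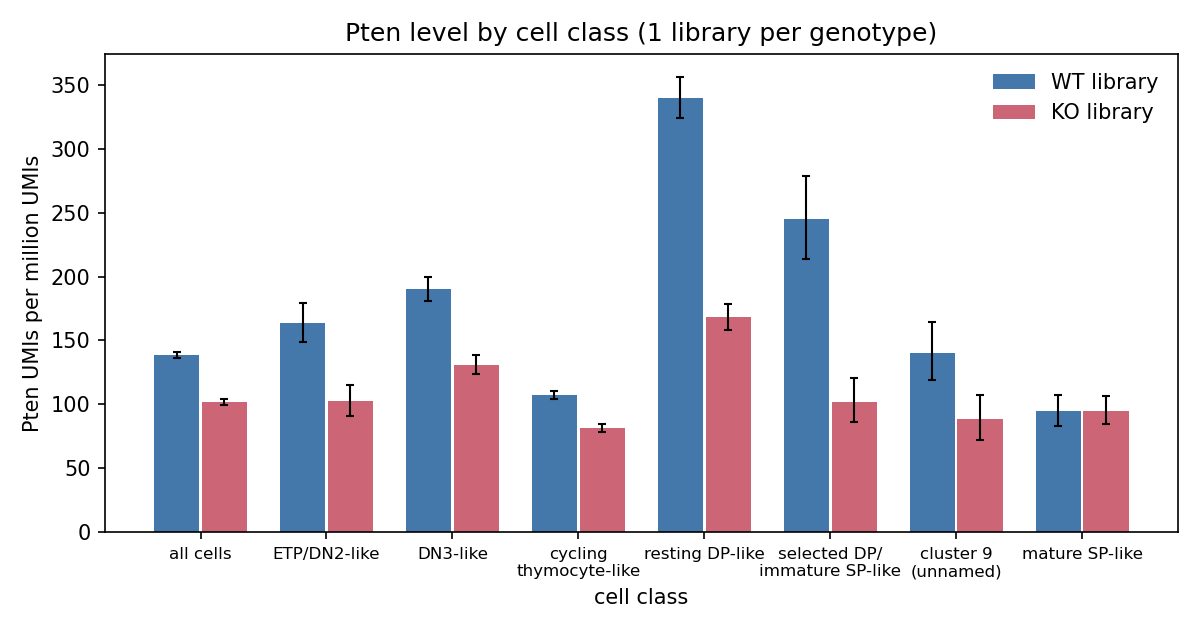
Pten level in UMIs per 1000000 UMIs (vertical axis) for all kept cells and single cell groups (horizontal axis), with 1 bar for the WT and 1 for the KO library; lines are exact 95% Poisson intervals, which cover counting error only. The KO bar lies below the WT bar in every group shown but mature SP-like cells, where the levels were 94.6 and 95.1 CPM.

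Most genes next to Pten on chromosome 19 did not share its difference over all cells. Of 19 listed neighbours, 12 reached 20 UMIs over all cells. Atad1, directly upstream, had a ratio of 0.982 (0.932 to 1.04), Minpp1 0.98 (0.93 to 1.03) and Pank1 0.967 (0.837 to 1.12). Rnls had 0.758 on only 23 and 14 UMIs, with an interval of 0.361 to 1.54. Higher in the KO library were Papss2 (1.59), Stambpl1 (1.24), Ankrd22 (1.62, 0.869 to 3.06), the death receptor Fas (1.47), the lysosomal lipase Lipa (1.43) and the interferon-induced Ifit1 (1.5), Ifit2 (1.36) and Ifit3 (1.57). These ratios also carry the different cell mix of the libraries, and the median log2 ratio of all genes over all cells was 0.15 (0.00481 when scaled by the median of gene ratios). Within resting DP-like cells Fas had 1.01 (0.921 to 1.1), Lipa 1.05 (0.986 to 1.12) and Atad1 0.835 (0.716 to 0.974). In cycling thymocyte-like cells Fas had 1.3 (1.11 to 1.51) and Lipa 1.28 (1.16 to 1.41). In mature SP-like cells they had 1.54 (1.2 to 1.99) and 1.18 (0.937 to 1.5). They had 1.14 and 0.986 in DN3-like and 1.06 and 1.01 in selected DP or immature SP-like cells, with intervals that held 1. The median log2 ratio of the neighbour list ran from 0.011 to 0.27 (25.1 to 99.2) over the named classes (percentile among random lists of like expression in brackets), and it turned below 0 in resting DP-like cells under the strict cell filter (−0.21) and averaged within clusters (−0.20), in selected DP or immature SP-like cells (down to −0.12, with the automatic doublet threshold) and in DN3-like cells (down to −0.061, in thinned cells).

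The second question was whether the libraries differed in their cell makeup. The KO library held a smaller share of cycling thymocyte-like cells and larger shares of resting DP-like, selected and mature SP-like cells. Every share depends on the 1:1 mix and on how well the depletion worked. The shares of a library sum to the whole, so a smaller share of cycling cells by itself raises the others. Cycling thymocyte-like cells made up 27.1% (26.1 to 28.1) of WT and 18.1% (17.1 to 19.1) of KO cells (exact Clopper-Pearson intervals). The difference lay in the cycling clusters low in Cd8a and Il2ra, at 20.9% (19.999 to 21.9) and 11.8% (11 to 12.7). The Cd8a-high cycling clusters held 4.15% and 4.41%, and the Il2ra-high one 2.03% and 1.87%. Resting DP-like cells made up 31.7% (30.6 to 32.7) and 37.3% (36 to 38.5), selected DP or immature SP-like cells 5.01% (4.52 to 5.54) and 7.24% (6.58 to 7.94), and mature SP-like cells 6.39% (5.83 to 6.97) and 8.53% (7.82 to 9.28). DN3-like cells were at 16.6% (15.8 to 17.5) and 15.2% (14.3 to 16.2), and ETP/DN2-like cells at 3.31% and 3.21%.

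Among the ETP/DN2-like, DN3-like and cycling cells alone, the cycling class held 57.6% (55.9 to 59.3) and 49.6% (47.4 to 51.7) and DN3-like cells 35.4% (33.8 to 37) and 41.7% (39.5 to 43.8). The unnamed cluster 9 held 3.83% and 4.05%, cluster 11 3.1% and 2.9996% and cluster 18 0.508% and 0.872%. Of the resting DP-like cells, 71.9% and 29.4% lay in cluster 1 and 28.1% and 70.6% in cluster 2. Macrophage or monocyte-like cells made up 0.7004% and 0.401%, B-like cells 0.357% and 0.576%, granulocyte-like cells 0.371% and 0.436%, innate T-like cells 0.824% and 1.03% and gamma-delta T-like cells 0.179% and 0.0523% of WT and KO. The cell filters removed 12.2% (11.5 to 12.9) of WT and 16.4% (15.6 to 17.3) of KO barcodes, most of them by their mitochondrial share.

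**Figure D2:**
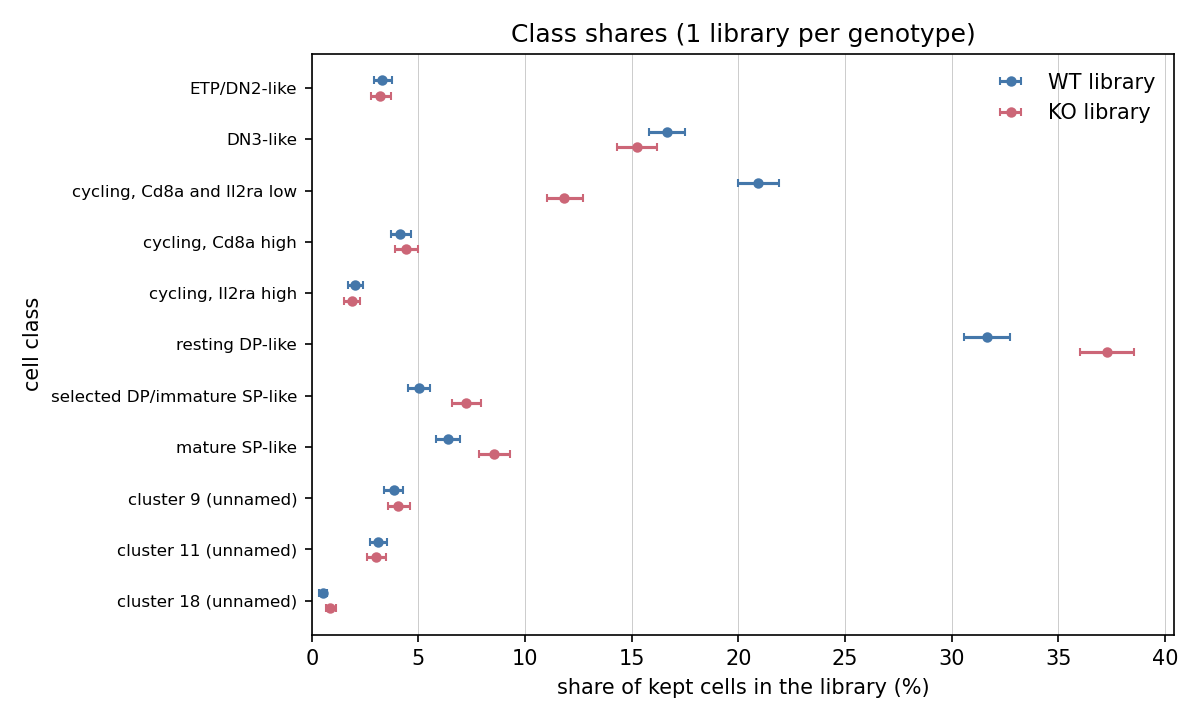
Share of kept cells in each cell class in percent (horizontal axis) for the WT and the KO library, 1 point each; lines are exact binomial 95% intervals, which cover counting error only. The cycling clusters low in Cd8a and Il2ra held 20.9% and 11.8%, and resting DP-like cells 31.7% and 37.3% of WT and KO cells.

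Phase calls from S and G2/M gene scores were fewer in the KO library over all cells; within classes the difference depended on the depth used, and the cycling class was near its ceiling in both libraries. With every cell thinned to 2000 UMIs, 50.9% of 6049 WT cells and 39.2% of 5535 KO cells were called S or G2/M; 1233 and 199 shallower cells were left out. The unthinned values were 43.6% and 32.6%. Within classes the thinned values were 27.7% and 28% in DN3-like, 99.6% and 99.8% in cycling thymocyte-like, 17.9% and 18% in selected DP or immature SP-like and 16.7% and 12.8% in mature SP-like cells. In DN3-like cells the parts went opposite ways, with S calls at 8.4% and 11.6% and G2/M calls at 19.3% and 16.4%. Resting DP-like cells had 21.7% and 21.3%, but 24.9% and 17.7% without thinning and 29.6% and 16.5% at 3000 UMIs, where 2100 WT and 1428 KO cells were too shallow. Only 1.48% and 1.42% of the resting DP-like cells thinned to 2000 UMIs were called S. Mki67 stood at 17.2 and 11.3 CPM in clusters 1 and 2, against 169 CPM or more in each cycling cluster. The calls in resting DP-like cells therefore cannot be read as a share of dividing cells. Mature SP-like cells had 11% and 4.29% without thinning. At 3000 UMIs the selected DP or immature SP-like cells had 24.7% and 17.1%.

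Resting DP-like cells, the largest class, are quiescent cells that rearrange the T cell receptor alpha chain. Besides Pten, a granzyme was lower in the KO library. Mitochondrially encoded genes were higher, as in every compared class. Interferon-induced and ribosomal protein genes were lower where clusters 1 and 2 were pooled. The lowest ratios were those of Gzma (0.48, 0.405 to 0.568; also a leading gene of cycling cluster 6), Pten, Slc6a19 (0.591), Ms4a6b (0.62), the tubulin gene Tubb2b (0.625), Slfn2 (0.688), Dnajc15 (0.693), Wdr89 (0.703), Epsti1 (0.722) and Mrps5 (0.742). Ifi209 (0.582) and Rpl9-ps6 (0.723) share 45.2% and 92.1% of their 3′ end with other genes, so their counts are uncertain. The highest were Tsc22d1 (1.66, 1.37 to 2.03), Art1 (1.57), Abtb2 (1.57), Nav2 (1.51), Smoc1 (1.51), Nfyc (1.49), Traf7 (1.49) and Ptcra, the pre-T cell receptor alpha chain (1.5, 1.28 to 1.76); Art1 had 1.03 under a strict cell filter, and Smoc1 2.71 in thinned cells and 0.909 when averaged within clusters. Tubb2b and Smoc1 are among the leading genes of clusters 1 and 2. Adrm1 (1.64), Erh (1.61), the enolase gene Eno1 (1.6) and Hmgn2 (1.49) have near-identical copies and are uncertain.

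Among the gene lists in resting DP-like cells, ribosomal protein genes were lower in the KO library in 76 of 79 measured members (median log2 ratio −0.20, percentile 0), such as Rps24 (0.789), but averaged within clusters their median was 0.00080. Interferon-induced genes were lower in 13 of 18 (median −0.12, percentile 0.21; −0.024 averaged within clusters), with Ifi203 at 0.80003 (0.691 to 0.926). Oxidative phosphorylation genes were lower in 40 of 58 (median −0.040, percentile 0.925), which turned to 0.045 within clusters. Clusters 1 and 2 divide largely by library, so averaging within them can also remove a difference between the libraries. The mitochondrially encoded genes were higher in 12 of 13 (median 0.18, percentile 99.99), led by mt-Atp8 (1.57 (1.43 to 1.71)). Granulocyte markers were higher in 5 of 5 (median 1.70, percentile 100), with S100a9 at 8.42 and 27.4 CPM. S100a8 and S100a9 lead the granulocyte-like cluster 21, and the part of these counts that came from other cells was not measured. The joint list of non-thymocyte markers was higher in 18 of 30 (median 0.096, percentile 79.9, and −0.12 under the strict filter).

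DN3-like cells rearrange the T cell receptor beta chain and depend on Notch signals. Cholesterol synthesis genes were lower and S phase genes higher in the KO library, and each difference nearly vanished or turned under 1 alternative. The class joined clusters 3 and 16, the latter led by the interferon-induced Ifi44, Isg15 and Ifit1. The lowest ratios were those of Khdc1a (0.492, 0.451 to 0.535), the imprinted transcript H19 (0.498, 0.449 to 0.552; 0.902 under the strict filter), Tshz2 (0.544), Capg (0.598), Hdgfl3 (0.606), Mcub (0.66), Mpzl2 (0.66) and the survival gene Bcl2 (0.664, 0.616 to 0.715). Khdc1a, H19 and Tshz2 are among the leading genes of cluster 3. The highest were Ide, the insulin-degrading enzyme (1.95, 1.7 to 2.25), Dqx1 (1.54; 0.39 under the strict filter), the mitochondrial leucyl-tRNA synthetase Lars2 (1.42) and Rab1a (1.4). Gstp1 (2.17), Erh (1.73), AC160336.1 (1.63) and Hmgn2 (1.54) have near-identical copies.

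Of the Notch targets in DN3-like cells 6 of 16 were higher (median log2 ratio −0.032, percentile 20.1), so the list as a whole showed no clear difference: Dtx1 (0.763 (0.676 to 0.862)), Il2ra (0.824 (0.797 to 0.853)) and Hes1 (0.838 (0.805 to 0.872)) were lower and Tcf7 (1.27 (1.22 to 1.33)) higher. S phase genes were higher in 32 of 42 (median 0.22, percentile 100; 0.011 under the strict filter), for example Mcm5 (1.46) and Ung (1.5), while G2/M genes were lower in 27 of 46 (median −0.056, percentile 0.24; 0.15 under the strict filter and 0.029 in thinned cells). Genes induced by T cell receptor signals were higher in 12 of 15 (median 0.37, percentile 100; Nfkbid 1.53), but at −0.15 under the strict filter and −0.089 with the automatic doublet threshold. The rearrangement and DP identity list was higher in 15 of 21 (median 0.14, percentile 99.96), led by Cd4 (2.28, from 3.25 and 7.39 CPM), Cd8b1 (1.85, 16.2 and 29.998 CPM) and Cd8a (1.59, 12.2 and 19.3 CPM), and stood at −0.00036 with that threshold. These genes were far more abundant in resting DP-like cells (Cd4 at 748 and 989 CPM in clusters 1 and 2), and the part of the DN3-like counts that came from other cells was not measured. Cholesterol synthesis genes were lower in 16 of 24 (median −0.080, percentile 0.0600; Msmo1 0.719, Ldlr 0.79), turning to 0.0094 with it. Markers of non-thymocyte cells were higher in 27 of 39 (median 0.31, percentile 100), and at −0.0057 in thinned cells and −0.049 under the strict filter. Mitochondrially encoded genes were higher in 11 of 13 (median 0.19, percentile 100) and ribosomal protein genes lower in 54 of 80 (median −0.033, percentile 9.51).

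Cycling thymocyte-like cells include the proliferating stages between DN3 and DP. Over its pooled clusters the KO library was higher in genes of DP identity and in genes that FOXO factors activate, by much less within clusters, and lower in Pten, Myc and some cholesterol synthesis genes. The lowest ratios besides that of Pten were those of Wdr89 (0.769, 0.748 to 0.791), the cholesterol synthesis enzyme Hmgcs1 (0.802), the signalling adaptor Sh2d1a (0.824) and the growth regulator Myc (0.841, 0.809 to 0.874). Rpl36a-ps1 (0.715), Hist1h2an (0.848) and Rpl9-ps6 (0.848) are uncertain, as their 3′ ends have near-identical copies. The highest were Ide (1.94, 1.85 to 2.05) and the chemokine receptor Ccr9 (1.76, 1.66 to 1.86) and, with copies, Gstp1 (2.28), AC160336.1 (1.87), Erh (1.7), Eno1 (1.64), Adrm1 (1.64) and Dynlt1f (1.64).

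Rearrangement and DP identity genes were higher in the KO library in 21 of 21 members in cycling thymocyte-like cells (median log2 ratio 0.21, percentile 100), with Cd4 at 2.02 (1.84 to 2.22), Cd8a at 1.45 (1.4 to 1.5), Rag2 at 1.3 and Tcf7 at 1.23. These ratios carry the mix of cycling clusters, since Cd8a-high clusters took a larger part of the class in KO, and averaged within clusters the median was 0.067. FOXO-activated genes, which PI3K signalling restrains, were higher in 17 of 23 (median 0.20, percentile 99.5; 0.053 averaged within clusters), such as Bcl6 (1.84), Btg1 (1.4) and Pik3ip1 (1.24), against Ctla4 (0.433, 0.35 to 0.532). Cholesterol synthesis genes were lower in 14 of 24 (median −0.042, percentile 0), with Msmo1 at 0.701 and Insig1 at 0.819. S phase and G2/M genes were higher in 34 of 42 (median 0.076, percentile 98.5) and 44 of 52 (median 0.088, percentile 99.9); the median of all genes in this class was 0.090. Interferon-induced genes were higher in 21 of 25 (median 0.24, percentile 99.7; Ifit1 1.9), and at −0.022 under the strict filter. Apoptosis regulators were higher in 18 of 22 (median 0.18, percentile 99.5; 0.063 averaged within clusters), mitochondrially encoded genes in 12 of 13 (median 0.13, percentile 99.97), and ribosomal protein genes lower in 67 of 79 (median −0.087, percentile 0). Markers of non-thymocyte cells were higher here too, in 42 of 48 (median 0.28, percentile 99.96, and 0.048 in thinned cells). Granulocyte markers were raised most (median 1.26, percentile 100, with S100a9 at 4.47 and 10.1 CPM). The part of these counts that came from other cells was not measured.

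Selected DP or immature SP-like cells carry signs of T cell receptor signalling. They numbered 365 in WT and 415 in KO, so single genes rest on few UMIs. After Pten, the lowest ratios were those of Ms4a6b (0.556, 0.428 to 0.722), Wdr89 (0.641), Tmed7 (0.65), Banf1 (0.662), Acat1 (0.679), Mprip (0.689; 1.09 under the strict filter) and the chromatin protein Hmgb2 (0.69). The highest were Lzic (1.95, 1.35 to 2.87), Diexf (1.93), the dynein chain Dnah8 (1.91), the cholesterol synthesis enzyme Dhcr7 (1.84), Mtmr3 (1.77), Bbx (1.7), the creatine kinase Ckb (1.68) and Erh (1.76, with copies). Ckb, a leading gene of cluster 9, lay at 0.905 under the strict filter, 0.968 with cycle genes left out of the clustering, 1.03 with no filter, 1.03 with classes set by WT cells and 1.06 with the automatic doublet threshold. Genes induced by T cell receptor signals were higher in 12 of 19 (median log2 ratio 0.15, percentile 98.6; 0.026 as the mean over cells), among them Cd69 (1.47, 1.25 to 1.74) and Nr4a1 (1.43, 1.14 to 1.82), while Egr2 was lower (0.683, 0.51 to 0.914). Ribosomal protein genes were lower in 76 of 79 (median −0.22, percentile 0), and markers of non-thymocyte cells higher in 12 of 20 (median 0.26, percentile 99.3; 0.076 over members with at least 100 UMIs).

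Mature SP-like cells (465 and 489 cells, clusters 8 and 13) differed most in cell cycle genes, which were lower in the KO library and rested on few cells. The proliferation gene Mki67 had a ratio of 0.341 (0.246 to 0.468), but 0.785 without doublet removal and 0.762 with the automatic doublet threshold. Top2a had 0.466 (0.37 to 0.586), and 0.803 and 0.77 under these. Hmgb2 (0.637), Atad2 (0.641) and Cks1b (0.641) were low too. S phase genes were lower in 32 of 39 (median log2 ratio −0.32, percentile 0; −0.13 as the mean over cells; Rrm2 0.237) and G2/M genes in 36 of 42 (median −0.34, percentile 0; −0.14 without doublet removal; Birc5 0.471). Mki67 UMIs came from 29 WT cells (130 UMIs) and 24 KO cells (58 UMIs). A step chosen after the values were seen left out the 10 cells per library with the largest part of UMIs in cycle genes. Without them the Mki67 ratio was 0.532 and that of the summed cycle genes 0.902, against 0.832 with them. Other low ratios were those of Plac8 (0.493), Tpm3-rs7 (0.672, with a copy) and Xcl1 (0.613; 0.263 under the strict filter, but 5.28 at resolution 1.6, 11.7 with cycle genes left out and 12.3 with classes set by WT cells). High ratios were those of the tetraspanin Cd82 (1.74, 1.4 to 2.17), Smg5 (1.65), the apoptosis inhibitor Birc2 (1.63), Odc1 (1.57; 0.844 at resolution 1.6), Chrac1 (1.55) and Fas (1.54, 1.2 to 1.99) and, with copies, AC160336.1 (2.09) and Erh (1.58). Genes induced by T cell receptor signals were higher in 13 of 20 (median 0.15, percentile 98.3), rearrangement and DP identity genes in 16 of 20 (median 0.13, percentile 98.2) and mitochondrially encoded genes in 12 of 13 (median 0.19, percentile 99.97; 0.056 under the strict filter), while ribosomal protein genes were lower in 65 of 79 (median −0.084, percentile 0.0100). Markers of non-thymocyte cells were higher in 20 of 27 (median 0.16, percentile 94.5). Rag1, of the rearrangement list, stood at 9.76 and 10.3 CPM in clusters 8 and 13, against 3179 and 3977 CPM in clusters 1 and 2. The part of the mature SP-like counts that came from other cells was not measured.

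In the unnamed cluster 9 (279 and 232 cells), Pten had the lowest ratio of the genes the naming rule ranks, with at least 50 CPM and 100 UMIs in a library. Among all genes within 2-fold of its level it was gene 5 of 2354. Next came Ddb1 (0.662), the actin regulator Gmfg (0.67, 0.574 to 0.78), Rcor1 (0.68), Ndufb2 (0.689), Rsl1d1 (0.694), Ndufab1 (0.695) and Rpl10-ps3 (0.696, with a copy). The highest were Eno1 (1.8, with a copy), Slfn5 (1.77, 1.28 to 2.48), Ncoa2 (1.68), Pwwp2a (1.67), Kansl2 (1.62), Zfr (1.6), Clec2i (1.59) and Spen (1.58).

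Lists around PI3K signalling and metabolism gave small differences. In resting DP-like cells PI3K, AKT and mTOR pathway genes were higher in 20 of 29 (median log2 ratio 0.087, percentile 82.6; −0.028 when averaged within clusters), with Gsk3a at 1.29 (1.16 to 1.43) and Tsc1 at 1.33 (1.06 to 1.66), while the PI3K subunit gene Pik3cd was at 0.633 (0.492 to 0.812). FOXO-activated genes were lower there in 13 of 22 (median −0.056, percentile 2.41), with Rag1 at 0.908 and Cdkn1b at 0.871, but the median was 0.10 in thinned cells. Over the named classes, with percentiles in brackets, the medians ran from −0.0097 to 0.11 (25 to 82.6) for the PI3K pathway, −0.065 to 0.20 (2.41 to 99.5) for FOXO-activated, −0.0033 to 0.078 (7.36 to 95.2) for MYC-activated, 0.055 to 0.15 (60.5 to 96.2) for glycolysis and −0.039 to 0.024 (8.72 to 26.4) for amino acid transport and ATF4 target genes. They ran from −0.090 to 0.044 (0 to 36.2) for cholesterol synthesis, −0.048 to −0.026 (0.61 to 15.2) for oxidative phosphorylation, −0.15 to 0.071 (8.88 to 71.8) for Notch target, 0.0031 to 0.16 (26.3 to 86.8) for p53 target, −0.035 to 0.084 (7.73 to 79.9) for dissociation stress and 0.0061 to 0.18 (34.7 to 99.5) for apoptosis genes. Each of these lists changed sign under at least 1 alternative in at least 1 class. Among markers of other cells the range was −0.036 to 0.31 (16.6 to 94.8) for plasmacytoid dendritic cells, 0.23 to 0.38 (89.6 to 99.2) for conventional dendritic cells, 0.29 to 0.54 (85.4 to 99.2) for macrophages or monocytes (−0.049 in DN3-like cells under the strict filter) and 0.047 to 0.27 (41 to 99.2) for B cells, the last 3 in the classes with enough UMIs. The sex-linked list could be read in cycling thymocyte-like cells only (median log2 ratio 0.25, percentile 96.4), and haemoglobin, erythroid and stromal genes had too few UMIs for a median, with 33 WT and 114 KO UMIs of Hbb-bs.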

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

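All tests in this part were chosen after the result was seen, except the comparison of Pten's gap with genes of like level. The Pten ratio went the other way in some classes: it was 1.01 in mature SP-like and 1.08 in innate T-like cells, where each other compared class lay below 1. Neither difference between classes was tested, as there was 1 library per genotype, and the intervals of both (0.845 to 1.20, and 0.636 to 1.85) hold 1. The cell cycle lists also went opposite ways between classes, untested: the S phase median log2 ratio was −0.32 in mature SP-like and 0.076 in cycling thymocyte-like cells, and that of G2/M genes −0.34 and 0.088. The cycling thymocyte-like values lay no higher than the median of all genes of that class, 0.0903, so their sign follows the scale. Against random lists of like expression (medians 0.0322 and 0.0312) they lay at percentiles 98.5 and 99.9. In mature SP-like cells these lists rest on few cells.

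The first pattern is that Pten was lower in the KO library in immature classes but not in mature SP-like cells. Free RNA from other cells as the source of Pten there would put its ratio at that of all cells, 0.735 (upper bound 0.758), but it was 1.01 with a lower bound of 0.845. A scale difference would move genes of like level, but their median log2 ratio was only 0.027 higher in mature SP-like than in resting DP-like cells. The makeup of the class is also argued against, since the ratio averaged over its clusters with WT weights was 1.00369. Of 780 genes of like level in both classes, 1 (0.128%), Pten itself, had a gap as low as its −1.02. Pten already ranked 1 of 1235 from the lowest ratio in resting DP-like cells (log2 ratio −1.01), so this comparison adds little to that rank. A stage-dependent part of the enhancer in Pten expression may underlie the pattern; with 1 library per genotype, a difference between individual mice stays open and was not tested.

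The second pattern is the smaller share of cycling cells low in Cd8a and Il2ra in the KO library. The larger loss of KO barcodes to the cell filters is argued against, as the KO minus WT difference of the cycling class was still −8.69 points with no filter. Without doublet removal the difference was −10.3 points, so doublet removal does not account for it. A smaller part of depleted cells in the KO mix stays open. It would lower all cells spared by the depletion alike; the KO to WT ratio of shares was 0.970 (0.803 to 1.17) in ETP/DN2-like cells and 0.929 (0.873 to 0.988) in these together with DN3-like, Il2ra-high cycling and cluster 11 cells, against 0.566 (0.520 to 0.615) in the cycling cells low in Cd8a and Il2ra. If these cells were spared alike, the values go against it as the only cause. A fall in the cycling cells by itself raises all other shares of a library, so a partial effect stays open. Cd3e stood at 385 CPM or more in each compared cluster and at most 330 CPM in those cycling clusters. The cells of those cycling clusters were deeper (WT medians of 22823 UMIs or more, against at most 18833 in the compared clusters), so CPM does not rank Cd3e per cell. Surface CD4 and CD3 were not measured. An effect of lower Pten on this stage, a difference between mice and a loss of these cells in handling may each lie behind it, and none of these was tested.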

How the results depend on the processing

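No paired analysis was possible because there was 1 library per genotype. Values with the automatic doublet threshold, averaged within clusters, or without copied genes in the totals come from alternatives chosen after seeing the data, as was the criterion for calling a list reversed. In the 6 Pten results all 78 alternatives that gave a value kept the side of the ratio or, for mature SP-like cells, stayed within its counting interval; 69 stayed within the interval and 9 moved out of it. Ratios ran from 0.450 to 0.507 in resting DP-like, 0.396 to 0.532 in selected DP or immature SP-like, 0.669 to 0.742 in DN3-like, 0.714 to 0.803 in cycling thymocyte-like and 0.923 to 1.15 in mature SP-like cells. Over all cells the Pten ratio moved to 0.665 with the median of gene ratios, 0.697 in thinned cells and 0.616 as the mean over cells. It moved to 0.45 in resting DP-like cells averaged within clusters and to 0.742 in DN3-like cells under the strict filter. In cycling thymocyte-like cells it was 0.714 with the median of gene ratios and 0.803 in thinned cells, and in selected DP or immature SP-like cells 0.532 with cycle genes left out and 0.521 with classes set by WT cells. The cause of these moves was not tested.

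The difference in the share of cycling cells ran from −10.3 to −7.95 points. The other 4 shares kept their direction under all 8 alternatives each, and 6 of these values moved out of the interval. Of 36 alternatives for phase calls 7 moved; at 3000 UMIs the difference over all cells was −15.8 points, in resting DP-like cells −13.1 and in selected DP or immature SP-like cells −7.60.

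Of 1681 alternatives for lists, 205 changed the sign of the median, 12 of them for lists that lay outside the middle 95% of random lists and whose counting interval excluded 0. Of these, 35 and 2 came from other totals or the median of gene ratios, which move all genes of a class alike and so say nothing of a list against other genes; 170 and 10 did not. Averaged within clusters, resting DP-like medians turned to 0.045 for oxidative phosphorylation and 0.00080 for ribosomal protein genes, so these depend on how clusters 1 and 2 are pooled. Those clusters were drawn without batch correction and divide largely by library (cluster 1 held 71.9% of WT and 29.4% of KO resting DP-like cells). Averaging within them can remove a difference between the libraries, so a cluster mix and such a difference cannot be told apart. In DN3-like cells the automatic doublet threshold gave 0.0094 for cholesterol synthesis, −0.089 for T cell receptor-induced and −0.00036 for rearrangement and DP identity genes. The strict filter, which keeps 251 WT and 126 KO DN3-like cells, gave −0.15 for T cell receptor-induced genes, and −0.049 for macrophage and −0.049 for all non-thymocyte markers (−0.0057 in thinned cells). In cycling thymocyte-like cells the strict filter gave −0.022 for interferon-induced genes. The median of gene ratios gave −0.013 for S phase and −0.00083 for G2/M genes there, as it moved the median of all genes from 0.0903 to 0.00116.

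Of 1175 alternatives for named genes 1050 stayed within the interval, 116 moved and 9 reversed. Reversed were Smoc1 (0.909 averaged within clusters) and, under the strict filter, Dqx1 (0.39), Ckb (0.905) and Mprip (1.09). So were Ckb with cycle genes left out (0.968), Odc1 at resolution 1.6 (0.844), and Xcl1 at resolution 1.6 (5.28), with cycle genes left out (11.7) and with classes set by WT cells (12.3). Where no cause is named, it was not tested. Of the 24 genes named in resting DP-like cells, 9 were also named with the looser and 9 with the stricter count minimum; of 16 each, 9 and 8 were in DN3-like, 7 and 7 in cycling, 1 and 4 in selected DP or immature SP-like and 4 and 4 in mature SP-like cells. All-cell ratios have no value under other clusterings or cluster averages, which cannot move them. Depth limits single genes most in the small classes.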

Other observations

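The cutoffs and both tests here were chosen after the result was seen. Some genes lay on the same side of the class median in every class in which they had at least 100 UMIs. Of 7963 genes measured in at least 3 of 5 classes, 31 were higher and 11 lower than the class median by more than 0.3 on the log2 scale in each, against at most 2 in 20 simulated draws. The draws hold counting error only, so the excess includes any difference between the mice or their preparation. Reads shared with near-identical copies may account for part of these, since 31.0% (17.6 to 47.1) of the 42 genes have such a copy, against 2.91% of all measured genes. Erh, Eno1, Gstp1, Adrm1 and Rpl10 are among them. The read lengths of the libraries are not in the sources used here, so a difference in them was not tested.

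Others have no copy. Ide had ratios of 1.71 to 2.16 and Fgfbp3 of 1.74 to 4.23, and Wdr89 of 0.641 to 0.825. Eps8l1 had 0.151 to 0.194 and Ly6k 0.371 to 0.445. S100a8 (1.72 to 3.01) and S100a9 (1.80 to 3.25), leading genes of the granulocyte-like cluster, were also among the higher genes. Fgfbp3 (36917550 to 36919615) and Ide (37268743 to 37337852) lie on chromosome 19, 4.09 and 4.44 megabases from Pten. A gain of 1 unbroken stretch from Fgfbp3 to Ide is argued against by March5. It lies between them and had a ratio of 0.990 (0.938 to 1.04) in cycling thymocyte-like cells. Btaf1, also between them, had 1.38 (1.28 to 1.49). The value of March5 cannot speak to a gain in separate parts that leaves March5 out, which stays open and was not tested. A difference between the mice in other genes stays open and was not tested.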
